A study of Glycine max with 30 samples.

How the data were processed

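The series measured poly(A) RNA from mature soybean (Glycine max) leaves in 30 libraries, which fall into 6 groups by the RNAi construct and the presence of the transgene. The sample titles name the lines GmNRPD1-RNAi, GmNRP(D/E)2-RNAi and GmNRPE1-RNAi; they are given here by the target in the sample descriptions, without the species prefix. In the NRPD1-RNAi family, of cultivar Jack, 3 transgenic plants were set against 3 non-transgenic siblings. In the NRP(D/E)2-RNAi and NRPE1-RNAi families, both of cultivar Mustang, 6 transgenic plants were set against 6 non-transgenic siblings each. Every family had its own control libraries, and no library served in more than 1 line's comparison. The labels gave no sowing date, sequencing lane or other batch, so a batch that followed a whole family could not be separated from that family.

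Total RNA was extracted with TRI Reagent, poly(A) RNA was selected on magnetic beads, and libraries were made with an NEBNext mRNA kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes named FastQC 0.11.5, STAR 2.5.3a and edgeR without a version and without the role of each. The authors deposited 1 table per library, holding a raw read count for each of 55589 Glyma gene identifiers, with no header. The counts were whole numbers and were not normalised. Genome build, annotation release, counting program, strandedness and read length were not given in the sources used here. Reads shared between near-identical copies, overlapping genes or antisense pairs could therefore have been counted for either gene, and values of single genes carry that uncertainty.

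No gene names stood in the count tables. None of the 55589 identifiers matched an entry of the NCBI RefSeq gene table used for names, which listed 59048 genes (matched: 0). Genes were therefore given by identifier, with at most 2 identifiers that rose and 2 that fell per comparison. The lists of gene families that had been set before the data were examined, and the check of each targeted subunit gene against the labels, needed names and were not analysed here. The chromosome of a gene was read from its identifier, and its position was given as its rank among the identifiers of that chromosome, not as a coordinate.

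Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. For each line, genes were kept by edgeR's filterByExpr with the groups as design, libraries were scaled by TMM (trimmed mean of M values), and transgenic and non-transgenic siblings were compared with edgeR's quasi-likelihood test, without a replicate block. P-values were adjusted by the Benjamini-Hochberg method, and a gene with an adjusted p under 0.05 is called. A joint model of the 6 groups over all 30 libraries tested whether the effect differed between lines, and compared the non-transgenic siblings of the Mustang families. CPM (edgeR's counts scaled to a common library total) were computed from the deposited counts with TMM scaling, within a line for the comparisons within lines and over all 30 libraries for the joint model and the values per library. Errors of log2 fold changes are standard errors derived from the edgeR F statistic, and errors of CPM are standard deviations over libraries.

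These choices, with the alternatives for the counts of called genes and the rule for naming genes, were fixed before the data were examined. The rule took, per line, genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and groups that did not overlap, ordered by absolute log2 fold change. For the overlap of the Mustang lines it took called genes ordered by the smaller of both absolute log2 fold changes, and every gene called the same way in all 3 lines. For the differences between lines and between control families, the largest log2 differences were taken by the same criteria, without the requirement on overlap for differences between lines. The rule allowed 10 genes each way; because the genes carry no names, only the first 2 each way are given.

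Several measures were added after the files had been read. Genes detected in each library were counted as the expected number with at least 1 count after thinning to the smallest library, of 10049997 counts, and compared within each line by two-sided exact permutation tests. A gene was taken as switched on when its mean in non-transgenic siblings was under 0.1 CPM and each transgenic library reached 0.5 CPM, and as switched off in the converse case, among genes that passed the filter of that line. Tested genes were grouped by their mean over all libraries of the line into classes of abundance. Lists of genes chosen in one line were also read in another over all their genes, without the expression filter, as mean CPM per group. Windows of 20 consecutive tested genes along a chromosome were compared with 10000 random placements of the same number of calls. The genes of the densest windows that passed the filter in both Mustang lines were averaged per library as log2 of CPM plus 1 and compared between siblings by exact permutation, and again over all genes of the window without the filter of the other line. Genes called the same way in both Mustang lines were then read in NRPD1-RNAi with limma's camera on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and again with an estimated correlation. Folds against a group with no count at all were computed against a floor of 3 counts over the group, with an exact 95% lower limit beside them. Folds against 1 to 3 counts are given with an exact 95% interval. Floors, limits and intervals cover counting error only.

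The edgeR tests and camera were tried on simulated data drawn gene by gene from the real means and library sizes. Up to 100 tested genes were changed at each fold. The window count was tried on simulated calls alone, and the other measures were not simulated. Of genes changed 2-fold, 1.01% were recovered in the NRPD1-RNAi simulation on 29881 genes, 50% in the NRP(D/E)2-RNAi simulation on 31465 genes and 27% in the NRPE1-RNAi simulation on 31039 genes. Of genes changed 4-fold, 25.3%, 89% and 80% were recovered in the same order, with 1, 5 and 5 false calls. Differences between the effects of both Mustang lines were recovered in 25% of genes at 2-fold and 79% at 4-fold, on 35412 genes. Between NRPD1-RNAi and NRP(D/E)2-RNAi the shares were 7% and 56%.

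Replicates were compared before they were averaged. Within each group the closest pair of libraries differed by a chi-square per degree of freedom of at least 6.57, far beyond sampling noise, and no library was counted as a duplicate. The design text describes the plants as siblings, and replicates were taken as separate plants; nothing in the labels says whether tissue was pooled. Alternatives covered another test, other scalings, other filters on low counts, a 2-fold minimum, a robust fit, all libraries in 1 model, the replicate number as a block and leaving out each library in turn. A limma voom fit with library quality weights and alternatives for the added measures were chosen after the data had been seen. No library was left out of the main comparisons.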

Results

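Leaf messenger RNA was profiled in soybean plants carrying RNAi constructs against subunits of RNA polymerases IV and V. These plant-specific polymerases act in RNA-directed DNA methylation, the pathway by which small RNAs guide DNA methylation to transposons and some genes. NRPD1 is the largest subunit of polymerase IV, NRPE1 is the largest subunit of polymerase V, and NRP(D/E)2 is the second subunit that both share. Each construct was studied in its own family, with transgenic plants and their non-transgenic siblings, 3 of each for NRPD1-RNAi in cultivar Jack and 6 of each for NRP(D/E)2-RNAi and NRPE1-RNAi in cultivar Mustang. The comparisons ask how leaf transcript levels differ between siblings with and without each construct, and whether the constructs share their effects. The transcript of each targeted subunit was not analysed here, because the identifiers in the count tables could not be paired with gene names, so the knockdown itself stands on the labels.

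The 30 libraries held between 10049997 and 21763621 counts over genes. Totals ranged from 12461936 to 13036316 in NRPD1-RNAi non-transgenic siblings and from 12204408 to 13743064 in transgenic siblings. In the NRP(D/E)2-RNAi family they ranged from 11172345 to 17950012 in non-transgenic and from 11398212 to 16788752 in transgenic siblings. In the NRPE1-RNAi family the ranges were 11697170 to 17961262 and 10049997 to 21763621. Total counts did not pass a two-sided exact permutation test between siblings in any line (NRPD1-RNAi p = 0.7, NRP(D/E)2-RNAi p = 0.996, NRPE1-RNAi p = 0.232).

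More genes were detected in transgenic than in non-transgenic leaves of both Mustang lines. At a common depth of 10049997 counts, NRP(D/E)2-RNAi plants expressed 39047 ± 491 genes (SD, n = 6) against 37510 ± 796 in their siblings, and each of the 6 transgenic libraries lay above all 6 controls. NRPE1-RNAi plants expressed 38858 ± 357 genes (SD, n = 6) against 37771 ± 332, with 5 of 6 transgenic libraries above all controls. In NRPD1-RNAi the means were 38974 ± 385 and 38377 ± 834 (SD, n = 3), a difference of 597 that was smaller than the spread of the controls. The 10 most abundant genes of each library took 3.17% ± 0.302 of the counts in NRP(D/E)2-RNAi transgenic leaves and 3.92% ± 0.328 in their siblings (SD, n = 6). Exact two-sided permutation tests gave p = 0.00217 for genes detected in NRP(D/E)2-RNAi, the smallest value 6 against 6 allows, 0.00433 in NRPE1-RNAi, and 0.00433 for the share of abundant genes in NRP(D/E)2-RNAi, each with a Benjamini-Hochberg value of 0.013 over the 9 library tests. The exact test in NRPD1-RNAi gave p = 0.4, where 3 against 3 cannot go below 0.1, and the share of the 10 most abundant genes gave exact p = 0.6 there and 0.864 in NRPE1-RNAi.

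**Figure D1:**
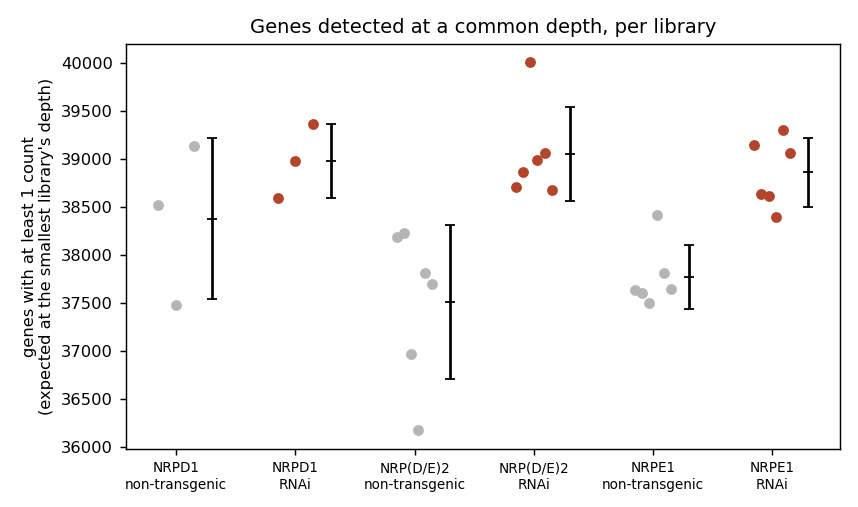
Genes with at least 1 count, estimated at the depth of the smallest library, for each of the 30 libraries, with the group mean and SD as a bar beside the points. All 6 NRP(D/E)2-RNAi libraries, between 38676 and 40002 genes, lie above their 6 controls, between 36176 and 38227.

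The line targeting the shared second subunit had the most called genes of the 3 lines, a count that also depends on the number of libraries and on their spread. Of 31773 genes tested in NRP(D/E)2-RNAi leaves, 5037 were called, 2734 higher in transgenic siblings with a median log2 fold change of 1.26 and 2303 lower with a median of −0.73. Among the 2360 called genes that changed at least 2-fold, 1675 were higher and 685 lower. Weakly expressed genes were mostly higher and abundant genes mostly lower: 71.3% of calls were higher under 1 CPM, 63.3% between 1 and 10 CPM, 48.5% between 10 and 100 CPM and 32.2% over 100 CPM, a share that became 51% under total count scaling. In addition, 54 genes that were off in non-transgenic leaves were on in every transgenic library, and 5 went the opposite way; all 54 and all 5 were among the called genes.

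Glyma.05G113500 had no count in any control and reached 71.1 ± 57.6 CPM in transgenic leaves (SD, n = 6, edgeR adjusted p = 0.000578). That was 2060-fold over the floor of 3 counts, with an exact 95% lower limit of 1780. Glyma.01G058400 rose from 0.0476 ± 0.0619 to 75.7 ± 41.7 CPM (SD, n = 6), a log2 fold change of 10.44 ± 0.56 (SE, edgeR adjusted p = 2.76e-07). Glyma.01G034200 fell from 15 ± 5.26 to 0.0894 ± 0.109 CPM (log2 fold change −7.29 ± 0.46, edgeR adjusted p = 8e-07), and Glyma.03G190800 from 29.5 ± 7.82 to 0.289 ± 0.107 CPM (−6.65 ± 0.28, edgeR adjusted p = 2.63e-08).

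The share of higher calls differed between the class over 100 CPM and the remaining calls by Fisher's exact test (adjusted p = 9.63e-13), and still did under total count scaling (p = 1.81e-08), which raised the share of higher calls among all genes from 54.3% to 69.4%. That share was 48.1% with all 30 libraries in 1 model (2456 higher, 2647 lower), so the balance of higher and lower calls turned with the model and the scaling. The number of calls fell to 2921 without transgenic replicate 3, to 3060 without transgenic replicate 2 and to 3220 without non-transgenic replicate 4.

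**Figure D2:**
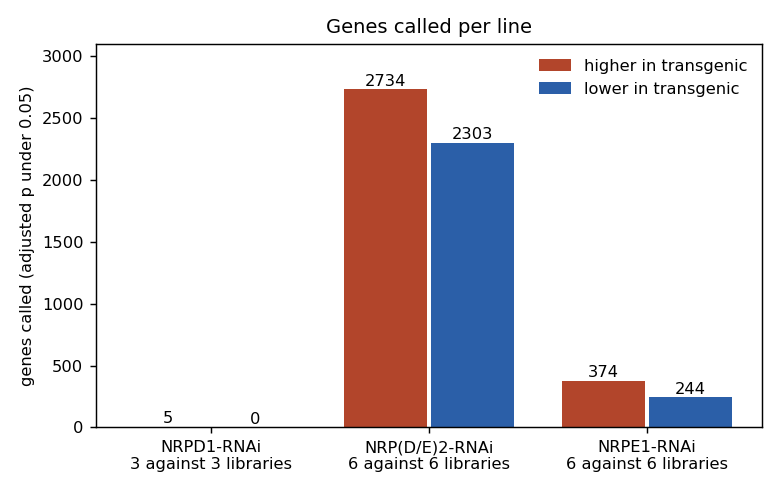
Number of called genes per line, higher (red) and lower (blue) in transgenic than in non-transgenic siblings, by edgeR at an adjusted p under 0.05. The bars show 2734 and 2303 genes in NRP(D/E)2-RNAi, 374 and 244 in NRPE1-RNAi, and 5 and 0 in NRPD1-RNAi, which had 3 libraries per group against 6 in the others.

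In NRPE1-RNAi leaves, with the largest subunit of polymerase V targeted, 618 of 31440 tested genes were called. Of these, 374 were higher with a median log2 fold change of 2.13, and 244 were lower with a median of −1.21; 470 changed at least 2-fold, 305 of them higher. By abundance, 66.9% of calls were higher between 1 and 10 CPM, 53.6% between 10 and 100 CPM and 31.8% of the 22 calls over 100 CPM. Leaves of transgenic plants expressed 41 genes that were off in their siblings, whereas 3 genes were on in siblings and off in transgenic plants, all of them called.

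Glyma.05G093900 was without a count in the 6 controls and reached 24.8 ± 28.9 CPM (SD, n = 6, edgeR adjusted p = 0.0327). That was 721-fold over the floor of 3 counts, with an exact 95% lower limit of 522. Glyma.09G107500 went from no count to 11.3 ± 2.24 CPM (SD, n = 6, edgeR adjusted p = 1.34e-05). That was 328-fold over the floor of 3 counts, with an exact 95% lower limit of 261. Glyma.14G195000 fell from 312 ± 162 to 2.84 ± 2.71 CPM (log2 fold change −6.78 ± 0.75, edgeR adjusted p = 0.000302), and Glyma.12G191700 from 12.3 ± 13.3 to 0.126 ± 0.129 CPM (−6.40 ± 0.88, edgeR adjusted p = 0.00166).

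On these 22 calls, direction in the class over 100 CPM passed Fisher's exact test against the remaining calls (adjusted p = 0.0118). The count of calls was 2102 without non-transgenic replicate 4, the control library with the most genes detected (38415), 1615 with DESeq2, 1415 with all libraries in 1 edgeR model and 3096 with voom weights, and Glyma.05G093900 lost its call without any 1 of 7 libraries, non-transgenic replicate 1, 2, 3 or 6 or transgenic replicate 3, 4 or 6, with edgeR adjusted p between 0.0504 and 0.0606.

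In NRPD1-RNAi leaves of cultivar Jack, 5 of 30539 tested genes were called, all of them higher in transgenic siblings. Glyma.17G224900 had 1 count over the 3 controls and 11.6 ± 3.69 CPM in transgenic leaves (SD, n = 3), a ratio of 453 with a 95% counting interval from 80.9 to 17900 (edgeR adjusted p = 0.0474). Glyma.06G286900 rose from 0.715 ± 0.445 to 73.7 ± 9.31 CPM (SD, n = 3), a log2 fold change of 6.69 ± 0.42 (edgeR adjusted p = 0.0316). At an unadjusted p under 0.05, 1903 genes were higher and 485 lower, and DESeq2 called 512 higher and 42 lower genes. The groups did not overlap in 13.2% of tested genes, where chance gives 10%.

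Transgenic replicate 3 stood apart from the other 5 libraries of this line on the first principal component, which held 53.8% of the variance. Without that library 54 genes were called; without transgenic replicate 1 or 2 or non-transgenic replicate 1 or 3 there were 0 calls, and 1 without non-transgenic replicate 2; Glyma.06G286900 lost its call with each of those 4 leave-outs at 0, and Glyma.17G224900 with all 5, and under total count scaling (edgeR adjusted p = 0.0608).

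Both Mustang lines changed many of the same genes in the same direction. Among 30396 genes tested in both, 216 were called higher in both lines and 131 lower in both, against 27.9 and 16.9 for independent lists, and 6 were called in opposite directions. The 347 shared genes made up 61.6% of the NRPE1-RNAi calls in that set, and 92.5% of the NRPE1-RNAi calls had the same sign in NRP(D/E)2-RNAi. The 216 shared higher genes had a median log2 fold change of 2.41 in NRP(D/E)2-RNAi and 2.61 in NRPE1-RNAi, and the 131 shared lower genes −1.37 and −1.40.

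Glyma.10G088100 had no count in any of the 12 Mustang controls. It reached 8.6 ± 3.83 CPM in NRP(D/E)2-RNAi and 5.65 ± 3.7 CPM in NRPE1-RNAi (SD, n = 6). These values were 250-fold and 164-fold over the floor of 3 counts, in that order. The exact 95% lower limits were smaller, at 201 in NRP(D/E)2-RNAi and under 164 in NRPE1-RNAi. Glyma.04G094700, likewise without a control count, reached 7.96 ± 2.77 and 5.12 ± 3.39 CPM in the same order of lines (SD, n = 6). Its folds over that floor were 231 and 149, with exact 95% lower limits of 188 and 116. Glyma.01G034200 was lower with log2 fold changes of −7.29 ± 0.46 and −5.36 ± 0.53, and Glyma.09G008400 with −5.15 ± 0.32 and −5.34 ± 0.54 (SE), in the same order of lines. Glyma.06G286900 was called in all 3 lines, with log2 fold changes of 6.69 in NRPD1-RNAi, 7.19 ± 0.72 in NRP(D/E)2-RNAi and 6.76 ± 1.03 in NRPE1-RNAi. It was the single gene called the same way in all 3.

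Fisher's exact test over genes gave p = 4.44e-149 for the shared higher and 9.9e-87 for the shared lower genes, treating genes as independent, which they are not. Across the 30396 genes tested in both, fold changes of the Mustang lines correlated with r = 0.636 (rho = 0.514). Over the genes tested in each other pair, r was 0.484 between NRPD1-RNAi and NRP(D/E)2-RNAi (28350 genes). Between NRPD1-RNAi and NRPE1-RNAi it was 0.3 (28460 genes). With DESeq2 calls the shared genes numbered 861.

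**Figure D3:**
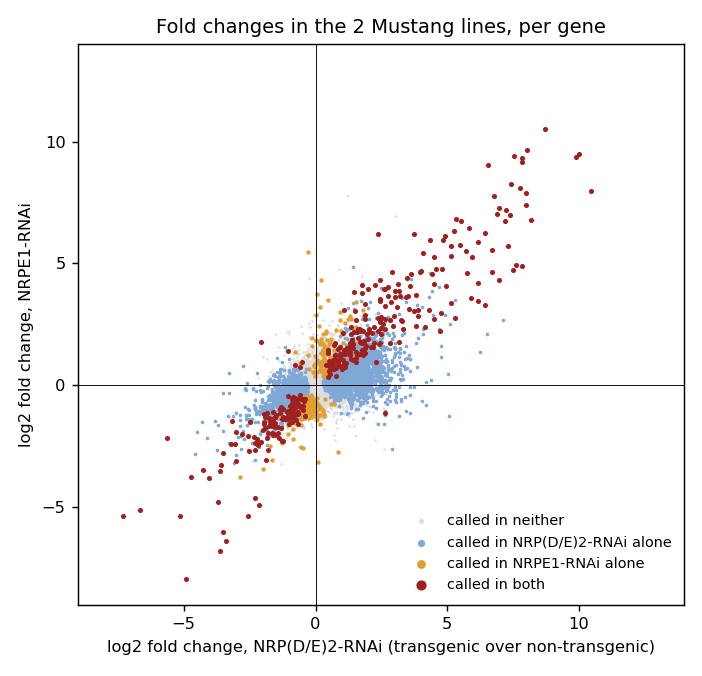
Log2 fold change of each gene tested in both Mustang lines, NRP(D/E)2-RNAi on the horizontal and NRPE1-RNAi on the vertical axis, coloured by the lines in which the gene was called. Of the genes called in both, 347 lie in the quadrants of equal sign and 6 in the others.

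Genes switched on in one Mustang line were also higher in the other. The lists hold genes that passed the filter of their own line, so the overlap counted from either list can differ. All 54 genes switched on in NRP(D/E)2-RNAi had a higher mean CPM in transgenic than in non-transgenic siblings of NRPE1-RNAi, read without a filter on expression there, and 26 of the 54 were switched on there too. Groups did not overlap for 42 of the 54, where chance gives 0.108% one way. Among all tested genes of NRPE1-RNAi, 2.19% did not overlap in either direction. Of the 41 genes switched on in NRPE1-RNAi, all 41 had a higher mean CPM in NRP(D/E)2-RNAi transgenic siblings, and 25 were switched on there. The test's filter kept 39 of the 54 and 25 of the 41 genes, of which 35 and 25 were called; that filter favours genes that rose, so these counts are no measure of overlap. In NRPD1-RNAi, 7 genes were switched on, of which 1 was called, and 1 was switched off; without a filter, 42 of the 54 had the higher mean in transgenic siblings of NRPD1-RNAi, 6 the lower and 6 no count, and edgeR called 0 of the 8 that passed its filter. The count of 7 rose to between 16 and 32 when a library other than transgenic replicate 3 was left out (16 without non-transgenic replicate 1, non-transgenic replicate 2 or transgenic replicate 2, 31 without non-transgenic replicate 3 and 32 without transgenic replicate 1).

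In NRPD1-RNAi, most of the genes shared by the Mustang lines shifted the same way. Of the 216 shared higher genes, 144 were tested, 118 (81.9%) were higher and their median log2 fold change was 0.43; 24 were called when adjusted over the list alone and 1 over all genes. Of the 131 shared lower genes, 122 were tested, 95 (77.9%) were lower and the median was −0.29; edgeR called 0 over the list alone or over all genes, with 18 lower and 2 higher at an unadjusted p under 0.05. Groups did not overlap in the direction of the list for 42 higher genes (29.2%) and 20 lower genes (16.4%), where chance gives 5%. Among all tested genes of this line the share was 13.2% in either direction, where chance gives 10%, and was not split by direction. The same 144 genes had medians of 1.75 and 2.00 and the same 122 genes −1.32 and −1.33 in NRP(D/E)2-RNAi and NRPE1-RNAi, where the genes had been selected, which inflates them; the difference between lines was not tested for the lists. Without a filter on expression, 175 of the 216 had the higher mean and 98 of the 131 the lower mean in transgenic siblings. These lists were chosen on the Mustang libraries and not on those of NRPD1-RNAi.

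Limma's camera gave p = 3.34e-16 for the higher and 2.94e-09 for the lower list with the preset correlation, and p = 0.00527 and 0.0117 with an estimated correlation, the former rising to p = 0.0683 without transgenic replicate 3. The labels were not the only grouping with this shift. A split that set non-transgenic replicate 3 with transgenic replicates 1 and 2 separated 67 list genes in the direction of the lists, against 62 for the real groups. The real groups separated more of the higher list (42 against 35), and that split more of the lower list (32 against 20).

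**Figure D4:**
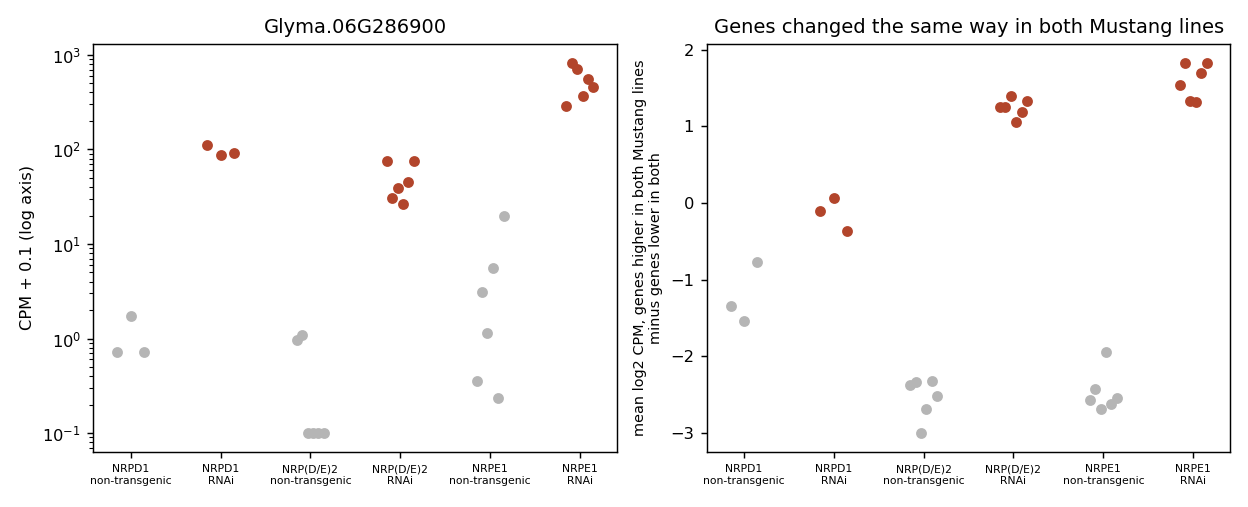
Left, CPM plus 0.1 of Glyma.06G286900 per library on a log axis; right, mean log2 CPM of the shared higher genes minus that of the shared lower genes per library, with transgenic libraries in red and non-transgenic ones in grey. The score of the NRPD1-RNAi libraries was −0.13 ± 0.21 in transgenic and −1.22 ± 0.40 in non-transgenic siblings (SD, n = 3), with non-transgenic replicate 3 at −0.775.

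Called genes were not spread evenly along the chromosomes. In NRPE1-RNAi, 36 genes of chromosome 16 were called higher and 6 lower among 1230 tested, an odds ratio of 1.82 against the other chromosomes. A stretch of 20 tested genes at ranks 1874 to 1936 of the 2223 genes on that chromosome held 13 genes called higher and 0 lower by edgeR, and 9 of the 17 genes that passed the filter in NRP(D/E)2-RNAi were called higher there as well. Over all 20 genes, without a filter, the mean log2 CPM rose by 1.83 in NRPE1-RNAi and by 1.06 in NRP(D/E)2-RNAi, where 6 of 6 transgenic libraries lay above all controls. In NRP(D/E)2-RNAi the densest stretch lay on the same chromosome at ranks 1687 to 1712, with 15 of 20 genes called higher and 0 lower, while 2 of the 20 were called in NRPE1-RNAi. The fold changes of those 20 genes were of like size in both lines, with a median of 1.58 in NRP(D/E)2-RNAi and 1.44 in NRPE1-RNAi. Their mean log2 CPM rose by 1.29 in NRP(D/E)2-RNAi and by 1.18 in NRPE1-RNAi, from 2.72 ± 0.77 to 3.9 ± 0.55 (SD, n = 6), with 4 of 6 transgenic libraries above all controls. Adjacent tested genes were called in the same direction 640 times in NRP(D/E)2-RNAi and 55 times in NRPE1-RNAi, against means of 402 and 6.31 under random placement.

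Fisher's exact test for chromosome 16 gave an adjusted p of 0.014 in NRPE1-RNAi and 0.0848 in NRP(D/E)2-RNAi over the 20 chromosomes. Random placement of the calls gave a permutation p of 1e-04 for higher genes in both windows, the smallest that 10000 placements can give, and 0.93 and 0.086 for the densest windows of lower genes. For the NRP(D/E)2-RNAi stretch, the difference in NRPE1-RNAi gave a two-sided exact permutation p of 0.0173. Without non-transgenic replicate 6 the densest window of NRP(D/E)2-RNAi lay on chromosome 7, with 12 genes.

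**Figure D5:**
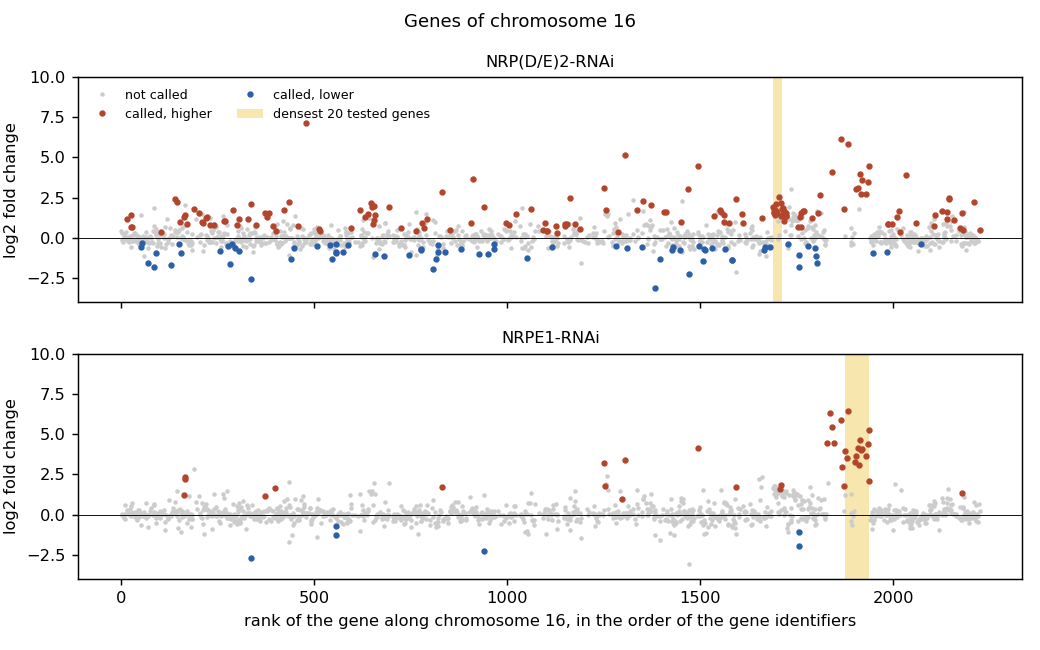
Log2 fold change of each tested gene against its rank along chromosome 16, for NRP(D/E)2-RNAi above and NRPE1-RNAi below, with called genes in red (higher) or blue (lower). The shaded stretches of 20 tested genes hold 15 and 13 genes called higher.

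Few genes were called when the difference in effect between lines was itself tested. In simulation, this test recovered 25% of 2-fold and 79% of 4-fold differences between the Mustang lines. Between NRPD1-RNAi and NRP(D/E)2-RNAi it recovered 7% and 56%. Few calls therefore do not show that the effects were alike. Between both Mustang lines, 61 of 36186 genes were called, 36 with the more positive and 25 with the more negative effect in NRPE1-RNAi. Glyma.15G235900 went from 6.9 ± 1.49 to 300 ± 166 CPM in NRPE1-RNAi and from 13.1 ± 3.88 to 10.4 ± 2.86 CPM in NRP(D/E)2-RNAi (SD, n = 6), a log2 difference of 5.78 ± 0.41 (edgeR adjusted p = 1.56e-09). Against NRPD1-RNAi, 131 genes were called for NRP(D/E)2-RNAi, 50 of them with the more positive effect there, and 129 for NRPE1-RNAi, 54 of them more positive. Glyma.03G190800 stayed at 12 ± 1.76 and 11 ± 1.48 CPM in NRPD1-RNAi (SD, n = 3) while it fell from 25.9 ± 7.07 to 0.247 ± 0.0929 CPM in NRP(D/E)2-RNAi (SD, n = 6), a log2 difference of −6.55 ± 0.41 (edgeR adjusted p = 9.11e-11).

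DESeq2 called 293, 339 and 337 genes for these differences in the same order. Regrouping siblings within the lines gave as many calls in 3 of 40, 5 of 40 and 5 of 40 draws, the real grouping included.

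Control plants of the Mustang families differed more from each other than from their transgenic siblings in the number of called genes. Between non-transgenic siblings of the NRPE1-RNAi and NRP(D/E)2-RNAi families, 14441 of 36186 genes were called, 7374 higher and 7067 lower in the NRPE1-RNAi family, and 7717 differed at least 2-fold. Glyma.10G168200 stood at 192 ± 63.9 against 0.0878 ± 0.0777 CPM and Glyma.16G094000 at 21.6 ± 7.08 against 0.0276 ± 0.0444 CPM (SD, n = 6). Glyma.11G229700 stood at 0.104 ± 0.0553 against 82.8 ± 16.8 CPM and Glyma.13G357500 at 0.0778 ± 0.121 against 56.8 ± 18.2 CPM (SD, n = 6).

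The log2 differences of these genes were 10.93 ± 0.66, 9.14 ± 0.94, −9.53 ± 0.51 and −9.18 ± 0.48 in that order, with edgeR adjusted p between 8.05e-14 and 1.46e-08. Family, and any batch that went with it, cannot be told apart in this comparison, and it was for this reason that each transgenic group was set against its own siblings.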

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

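Among the tests of this part, these were chosen only after the result was seen: reads from the construct, the splits of each line, of the control families and of both Mustang lines together, transgenic replicate 3 standing apart, the swap of replicate 3, the single genes read against it, and the shift of the dense stretches per library.

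Single libraries stood far from the rest of their group in 20 of 105 groups tested by the gap to the nearest library, each time as the highest of its group. Chance gives about 5% for values with a symmetric spread, a reference that does not hold for CPM near 0, where a single count can set a library apart. Transgenic replicate 3 of NRP(D/E)2-RNAi had 40002 genes detected, the highest of its group. Non-transgenic replicate 4 of NRPE1-RNAi had 38415 genes detected and a score of −1.94 for the genes shared by the Mustang lines, the highest among its siblings in both measures.

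The remaining libraries that stood apart did so in single genes, each as the highest of its group on the CPM scale of all 30 libraries. In NRP(D/E)2-RNAi non-transgenic siblings these were Glyma.09G107500 at 0.0507 CPM in replicate 1, the single count of that group, Glyma.01G034200 at 22.6 CPM in replicate 3, Glyma.07G192400 at 14.2 CPM and Glyma.13G317600 at 1.51 CPM in replicate 4, and Glyma.12G191700 at 146 CPM in replicate 6. In its transgenic siblings they were Glyma.04G094700 at 11.4 CPM in replicate 1 and Glyma.19G146800 at 17.2 CPM in replicate 3. In NRPE1-RNAi non-transgenic siblings they were Glyma.14G195000 at 639 CPM in replicate 2 and, in replicate 4, Glyma.03G190800 at 30.5 CPM, Glyma.07G192400 at 2.55 CPM and Glyma.13G357500 at 0.313 CPM. Replicate 6 of that group held Glyma.06G286900 at 19.8 CPM and Glyma.05G113500 at 0.151 CPM. In NRPE1-RNAi transgenic siblings they were Glyma.09G008400 at 0.603 CPM and Glyma.13G317600 at 13.3 CPM in replicate 1, Glyma.10G168200 at 134 CPM in replicate 3, and Glyma.12G191700 at 0.367 CPM in replicate 6.

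The effect of the transgene differed between the Mustang lines for 61 genes, and chance was not excluded: 3 of 40 regroupings of siblings within the lines gave as many calls, with up to 881 in another regrouping. For NRPD1-RNAi against NRP(D/E)2-RNAi the count was 131, with 5 of 40 regroupings as large and up to 1612 in another, and chance was not excluded. For NRPD1-RNAi against NRPE1-RNAi it was 129, with 5 of 40 as large and up to 776, and chance was not excluded there either. These regroupings also mixed or reversed the transgene label within each line, and both Mustang lines had many called genes. Counts in other draws can therefore come from those differences between siblings. The regroupings cannot decide whether chance gave the real counts, and no conclusion is drawn from them.

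Between the Mustang lines, the effect was more positive in NRPE1-RNAi for Glyma.15G235900 (log2 difference 5.78 ± 0.41, SE, edgeR adjusted p = 1.56e-09) and Glyma.07G192400 (4.16 ± 0.68, edgeR adjusted p = 0.00294), which went from 0.649 to 14.3 CPM in that line. It was more negative there for Glyma.13G317600 (−4.52 ± 0.82, edgeR adjusted p = 0.0084) and Glyma.20G115900 (−4.46 ± 0.67, edgeR adjusted p = 0.00128). Against NRPD1-RNAi, the effect in NRP(D/E)2-RNAi was more positive for Glyma.01G058400 (10.84 ± 1.41, edgeR adjusted p = 9.56e-05) and Glyma.16G186400 (6.82 ± 1.33, edgeR adjusted p = 0.0132), and more negative for Glyma.08G355900 (−7.39 ± 1.67, edgeR adjusted p = 0.0435) and Glyma.03G190800 (−6.55 ± 0.41, edgeR adjusted p = 9.11e-11). Against the same line, NRPE1-RNAi had the more positive effect for Glyma.01G058400 (8.40 ± 1.37, edgeR adjusted p = 0.00191) and Glyma.09G107500 (6.97 ± 0.76, edgeR adjusted p = 3e-05). It had the more negative effect for Glyma.17G224900 (−7.87 ± 1.28, edgeR adjusted p = 0.00191) and Glyma.19G146800 (−7.52 ± 1.48, edgeR adjusted p = 0.014), which among the NRPD1-RNAi transgenic libraries had counts in replicate 3 alone, at 3.32 CPM. Fitted differences of genes with a group near 0, such as Glyma.09G107500 without a count in NRPE1-RNAi controls, depend on the prior count.

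In both Mustang lines, 347 genes changed the same way, 216 higher and 131 lower in transgenic siblings. Whether reads from the construct or vector raised some of the 216 higher genes was not tested. Such reads do not account for all 347 genes, because 37.8% of the 347 were lower. Of 100 splits of the siblings in both lines, 1 gave as many, the real one, and the highest other split gave 0. That outcome was fixed by NRP(D/E)2-RNAi, where each of the 99 other splits called 0 genes. The splits therefore do not test whether the overlap exceeds chance. A condition shared by siblings, such as growth stage, might stand behind part of them; in NRPD1-RNAi the groups differed in these genes by 1.43 times the larger range within a group. That ratio passed the bound of 1 set beforehand, but the bound was too weak, since a split of non-transgenic replicate 3 and transgenic replicates 1 and 2 from the rest separated 67 list genes and the real groups 62. By list the 2 groupings disagreed: the real groups separated 42 higher and 20 lower genes, and the other split 35 and 32. The effect of the RNAi constructs and a condition that followed the transgene cannot be told apart for these genes.

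Called genes lay densely in a stretch of chromosome 16 in each Mustang line. A segment that differed between the siblings of 1 line alone is argued against as the whole cause for both stretches by the shift of their genes per library in the other line. For the NRPE1-RNAi stretch the shift in NRP(D/E)2-RNAi was 0.586 times as large, or 0.58 times over all 20 genes without a filter (exact two-sided p = 0.00216, the smallest possible), and for the NRP(D/E)2-RNAi stretch the shift in NRPE1-RNAi was 0.917 times as large (exact two-sided p = 0.0173). The share of calls in the other line over its share among all genes, 3.34 and 5.09 in that order, was not used to decide, because it covers genes that passed the other line's filter and neighbouring genes are not independent. Tandem copies called together may contribute in both stretches. In either, 0% of the calls went the other way, which was predicted for such copies. Calls in 1 direction cannot tell copies from the other explanations, and gene copies were not examined. An effect of the constructs on linked genes remains open and was not tested.

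Few genes were called in NRPD1-RNAi, 5 against 5037 and 618 in the other lines. For fewer libraries alone, 50 subsets of 3 against 3 from NRP(D/E)2-RNAi gave a median of 376.5 calls and from 112 to 4042. Subsets of NRPE1-RNAi gave a median of 79.5 and from 3 to 860, with 2 of 50 at 5 calls or fewer. Fewer libraries alone are thus argued against for an effect as large as in NRP(D/E)2-RNAi. For a smaller effect the subsets do not decide. Transgenic replicate 3 standing apart is a candidate explanation, since 54 genes were called without it and at most 1 without any other library. Swapped labels of replicate 3 could not be decided: 4 of 11 genes switched on in a Mustang line were separated by the swap and 5 by the labels. A weaker effect in cultivar Jack or of this construct remains open as well.

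The splits of the NRPD1-RNAi libraries are too few for a share under 0.05: 2 of 10 gave as many calls, with 5 for the real groups and 439 for the highest other. That other split, of non-transgenic replicates 1 and 2 and transgenic replicate 3 from the rest, points to a structure of the samples. Single genes went both ways. Of 11 genes named in the Mustang lines, 3 were separated in the Mustang direction by the labels and 3 by that split, but 2 of the latter moved little: Glyma.03G190800 lay at 10.1 CPM in each of 3 libraries against 12.3 to 13.6 CPM, and Glyma.01G058400 at 0.672 to 1.76 CPM against 0 to 0.352 CPM. Among the genes that followed the labels, Glyma.09G107500 was at 0.512, 0.469 and 0.31 CPM in non-transgenic and at 4.59, 6.9 and 2.93 CPM in transgenic siblings, and Glyma.05G113500 at 0.205, 0.234 and 0.724 CPM and at 1.34, 3.11 and 7.41 CPM. Glyma.06G286900 and Glyma.17G224900, called under the labels and so picked for following them, were at 0.62 and 0.103 CPM in non-transgenic replicate 3 and at 91.3 and 19.8 CPM in transgenic replicate 3. Glyma.14G195000, read in this line only after its values were seen, followed the other split, at 153, 211 and 258 CPM in the former libraries and 1.24, 0.672 and 1.73 CPM in the latter, on the scale of all 30 libraries.

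Random grouping of the siblings is argued against for NRP(D/E)2-RNAi, with 1 of 100 splits as large, the real one (5037 calls, highest other 0). For NRPE1-RNAi it is as well, with 1 of 100 (618 calls, highest other 7). The non-transgenic siblings of the Mustang families also gave 1 of 100 splits as large, in a fit of those 12 libraries (11989 calls, highest other 0). A share of 1 of 100 is the smallest that 100 splits can give.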

How the results depend on the processing

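The voom fit with quality weights and the alternatives for switched genes, genes detected, shared lists, windows, abundance classes and family differences were chosen after the result was seen; the others were planned.

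Counts of called genes changed with the test, by more in NRPD1-RNAi and NRPE1-RNAi than in NRP(D/E)2-RNAi. In NRP(D/E)2-RNAi, DESeq2 gave 7371 and voom weights 5176 against 5037, and all libraries in 1 model 5103. Of the 5037 genes, DESeq2 kept 5013, voom weights 4087 and all libraries in 1 model 3609, so similar totals held partly different genes. In NRPD1-RNAi, 5 calls became 1 under total count scaling, 10 without a filter on low counts, 208 (199 higher, 9 lower) with all 30 libraries in 1 model, 554 with DESeq2 and 2336 (1830 higher, 506 lower) with voom weights. In NRPE1-RNAi, 618 became 1415 with all libraries in 1 model, 1615 with DESeq2 and 3096 with voom weights. A 2-fold minimum left 2360 of the NRP(D/E)2-RNAi calls and 7717 of those between control families, as a stricter criterion must. DESeq2 called 293, 339 and 337 genes for the differences between lines, and 861 genes the same way in both Mustang lines. For the remaining changes in this paragraph the cause was not tested.

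Leaving out 1 library at a time gave 0 to 54 calls in NRPD1-RNAi, 2921 to 5521 in NRP(D/E)2-RNAi and 441 to 2102 in NRPE1-RNAi. The lowest 0 came without non-transgenic replicate 1 or 3 or transgenic replicate 1 or 2, and 54 without transgenic replicate 3. In NRP(D/E)2-RNAi the lowest came without transgenic replicate 3. The highest in NRPE1-RNAi came without non-transgenic replicate 4, and the cause was not tested. The difference in genes detected ranged from 149 to 975 in NRPD1-RNAi, from 1269 to 1680 in NRP(D/E)2-RNAi and from 999 to 1217 in NRPE1-RNAi, with exact p up to 0.00649 in both latter lines.

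The replicate block, which takes equal replicate numbers as pairs, gave 0 calls with edgeR in NRPD1-RNAi, 2198 in NRP(D/E)2-RNAi, 293 in NRPE1-RNAi and 177 shared genes. The numbers do not appear to pair plants: deviations of equally numbered libraries correlated between −0.4 and 0.41 across genes, and a library was closest to its own number in 1 pair, replicate 6 of NRP(D/E)2-RNAi. Under the block, the share of higher calls over 100 CPM in NRPE1-RNAi was 54.5% (Fisher's exact p = 0.339), and Glyma.10G088100 and Glyma.04G094700 lost their NRPE1-RNAi calls (edgeR adjusted p = 0.059 and 0.0636).

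Log2 fold changes of named genes were recomputed under 402 alternatives over 20 results: 380 kept direction and side of the threshold, 21 lost the call, 1 gained it and 0 reversed. The gain was Glyma.01G034200 in NRPD1-RNAi with voom weights.

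The targeted subunit genes and the fixed gene lists were not run, since no identifier was paired with a name. Depth limits genes without a count in a group, whose folds rest on a floor of 3 counts. Expression below that floor was not detectable. In NRPD1-RNAi, simulated 2-fold changes were recovered in 1.01% of genes with 3 libraries per group, so small changes there went largely uncalled.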

Other observations

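The test for a mislabelled cultivar or family and the other limits for on and off were chosen only after the result was seen; the test for a growth or library batch was not.

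No gene switched off in a Mustang line was called in NRPD1-RNAi. Of the 5 genes switched off in NRP(D/E)2-RNAi, 4 were tested in NRPD1-RNAi, with a median log2 fold change of −1.16, and the 3 switched off in NRPE1-RNAi had a median of −0.94; these few genes were not tested as a group. EdgeR called 0 of these in NRPD1-RNAi, where 485 genes were lower at an unadjusted p under 0.05 and DESeq2 called 42 lower genes.

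Genes that were on in every library of 1 family and off in every library of the others, or the reverse, most often set apart the NRPD1-RNAi family. The NRPD1-RNAi family, of cultivar Jack, stood alone at 57 of 35557 genes, 30 on and 27 off, against 4 genes for the NRP(D/E)2-RNAi family and 1 for the NRPE1-RNAi family. A mislabelled cultivar or family was predicted to set a Mustang family apart at more genes, which these counts did not show. A batch that followed the NRPD1-RNAi family could set it apart whatever its cultivar, so the counts cannot decide the label. With other limits for on and off, the family of cultivar Jack still stood alone at the most genes: 104 against 27 and 1, and 13 against 0 and 0. Limits set on family means rather than on every library gave 263 against 76 and 11. The 4 genes named for the control families go the other way, with non-transgenic Jack siblings near those of NRPE1-RNAi: Glyma.10G168200 at 178 CPM, Glyma.16G094000 at 20.4 CPM, Glyma.11G229700 at 0.0391 CPM and Glyma.13G357500 at 0.0689 CPM. They were picked as the largest differences between the Mustang families. A growth or library batch stays open: at most 2 of the 57 genes fell within 20 consecutive genes, no more than the 95th percentile of 2 under random placement, and a cultivar difference could give the same. Mean profiles of non-transgenic siblings correlated across genes with r = 0.914 between the Mustang families, and with 0.765 and 0.826 between the NRPD1-RNAi family and the NRP(D/E)2-RNAi and NRPE1-RNAi families; genes are not independent replicates.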
